A study of Mus musculus with 48 samples.

How the data were processed

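Single cells of the aorta-gonads-mesonephros region of C57 wild-type mouse embryos at embryonic day 10 were sorted by FACS and kept on ice. Deformed cells were discarded, and living cells were moved 1 by 1 into lysis buffer with ERCC spike-in RNA. PolyA RNA was turned into full-length cDNA and sequenced on a Nanopore PromethION instrument. Per the labels, the processing used minimap2 2.18-r1015, Salmon 1.1.0 and genome build mm10; the annotation release and any filter on transcripts are not given in the sources used here. Each of the 48 tables the authors provided holds a signal per transcript for 1 cell, namely its reads per 10000 reads of that cell, over the same 52927 transcripts. The values of each cell summed to 10000, and 100% of them were whole multiples of the smallest value above 0 within 0.01 of a read, so whole reads and the depth of each cell were recovered. The tables used here held 0 ERCC transcripts, so spike-in shares were not analysed here.

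Transcript identifiers were looked up in GENCODE M21, the annotation of this build, which gave gene, symbol, position and transcript type for 52799 of them; the other 128 were left out of all gene and isoform comparisons. The matched transcripts belonged to 21435 genes, and 1254 of all transcripts were at 0 in every cell. The values of a gene's transcripts were summed. No pair of cells was identical, and the highest Pearson r between a pair of cells over genes was 0.919. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

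Cells were grouped by title, 24 AEC and 24 HEC, and HEC cells were compared with AEC cells. The labels name cells but no animals, so each group counted as 1 sample: no p-value, standard error or count of changed genes was computed, and SDs describe the spread between cells. For each gene the mean over the cells of each group was taken, and the log2 ratio of HEC over AEC was computed with a pseudocount of 0.1 on each mean. A gene or transcript counted as detected above 0; shares of cells are given for values of 1 or more, with exact Clopper-Pearson 95% intervals, in place of the share above 0 that was chosen first, because low values of some genes were found in every cell. Pooled levels from recovered reads carry exact Poisson 95% intervals. Precision is limited by depth, from 13261 to 8897958 reads per cell. The Poisson intervals cover counting error only. The Clopper-Pearson intervals treat the cells of a group as independent and leave out differences between animals.

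Genes were named by a rule. Among genes with a mean of at least 0.5 over the 48 cells and a value above 0 in at least 12 cells of a group, the 12 highest and the 12 lowest log2 ratios were named, leaving out sex-linked genes and gene models without a symbol. A set of 22 single genes was named whatever their values: *Runx1*, *Gfi1*, *Gfi1b*, *Myb*, *Kit*, *Ptprc*, *Cd44*, *Procr*, *Neurl3*, *Cdh5*, *Pecam1*, *Gja5*, *Dll4*, *Hey1*, *Hey2*, *Sox17*, *Notch1*, *Bmx*, *Efnb2*, *Srsf2*, *Srsf1* and *Srsf3*. Of each gene list, up to 4 members above 0 in at least 12 cells with the largest absolute ratio were named; other list members in the text were picked after their values were seen. A few genes that met these rules are not reported here.

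The 27 gene lists covered endothelial, arterial, venous and hemogenic genes, splicing factors (SR proteins, hnRNP proteins, core spliceosome, tissue regulators), cell cycle phases, ribosomal proteins, ribosome biogenesis, energy metabolism, inflammation, extracellular matrix, Notch signaling, dissociation stress, sex-linked genes, and markers of erythroid, macrophage, megakaryocyte, lymphoid, mesenchymal, neural and epithelial cells. A list's value is the median log2 ratio of its members with a mean of at least 0.1, with its percentile among 10000 random lists of the same size matched on level in 20 bins. Lists of imprinted genes, of serine, one-carbon and purine synthesis, caveolae, snoRNA host genes and chaperones were added after the values had been seen.

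Isoform shares were computed for 1032 genes with at least 2 transcripts, a mean of at least 1 in each group and a value above 0 in at least 12 cells of each group, as the percent of the gene's summed value over the cells of a group. The isoforms of the 8 genes with the largest differences were named, as were those with a share of at least 10% of *Runx1*, *Gfi1*, *Srsf2*, *Cd44*, *Kit* and *Ptprc* where the gene was detected in at least 6 cells of each group. Detected genes and isoforms per gene were also counted after thinning each cell at random to 10000 reads (all cells) and to 200000 reads (18 AEC and 23 HEC cells). For each cell the 5 cells with the highest Spearman correlation over the 1000 most variable genes were taken as neighbours.

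The groups, the 27 lists, the naming rule and most alternatives were chosen before the data were examined. The alternatives covered pseudocounts of 0.01 and 1, the difference of mean log2 values, median-of-ratios scaling over genes above 0 in at least 40 cells, totals without the 50 most abundant genes or without ribosomal protein and mitochondrial genes, leaving out single cells or the 6 cells of each group with the fewest genes, other list and isoform filters, and 3000 genes for the neighbours. Leaving out the 4 cells with *Cdh5* and *Kdr* both under 0.5 (AEC 11, 19 and 20 and HEC 20), leaving out both sets of cells, and stating list medians relative to the shift of all genes were added afterwards.

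The steps were tested on simulated data of the same shape. A made log2 change of 1 was recovered as 0.81 at the median (99.0% of genes in the right direction) and a made change of 2 as 1.81, with an SD of 0.40 among unchanged genes. All simulated genes had the same relative spread between cells, apart from read sampling. Some real genes varied more, such as *Hnrnpf* with a mean of 11.7 (SD 35.6) in AEC cells. A list of changed genes reached percentile 100 and an unchanged list 12.9. A made isoform change of 20 points was recovered as 19.9. The simulated isoforms had the same share in all cells of a group, apart from read sampling. Shares of real cells varied more, with an SD of 43.0 points between AEC cells for Ndufv2-201. The simulation therefore does not show how precise the measured log2 ratios or isoform differences are. The neighbours shared the label in 87.9% of cases when the groups differed and in 50.8% when they did not.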

Results

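Full-length cDNA of polyA RNA was sequenced on a Nanopore PromethION instrument from 48 single cells of wild-type C57 mouse embryos at embryonic day 10. The cells came from the aorta-gonads-mesonephros region, the part of the embryo in which the first hematopoietic stem cells arise. The titles place 24 cells in a group called AEC and 24 cells in a group called HEC. Neither abbreviation is spelled out in the labels; in this field they commonly stand for arterial endothelial cells and for hemogenic endothelial cells, the endothelial cells that give rise to blood. The cell type tag of the HEC cells names hematopoietic stem cells instead, so the groups followed the titles. The animal of each cell is not given in the sources used here, and each group therefore counted as 1 sample, with no test of any difference.

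The depth differed widely between cells. The median number of reads per cell was 769716 in AEC cells (range 13261 to 4883854) and 724674 in HEC cells (range 96410 to 8897958). The 6 shallowest AEC cells (AEC 1, 7, 8, 10, 12 and 21) held 13261 to 50126 reads, and a single read there stood for a value of up to 0.754 reads per 10000. All values are given as reads per 10000 reads of the cell. The median number of genes above 0 was 8317 in AEC cells (range 3348 to 12663) and 10645 in HEC cells (range 8008 to 15966). After thinning to 200000 reads, the medians were 6352 genes in 18 AEC cells (SD 871) and 8477 genes in 23 HEC cells (SD 868), a difference beyond the spread between cells. After thinning all cells to 10000 reads, the medians were 2809.5 and 3122.5 genes, which differed by less than the SD of 464 between AEC cells. At a value of 0.5 or more, the medians were 3203 and 3403.5 genes, which differed by less than the SD of 784 between AEC cells.

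**Figure D1:**
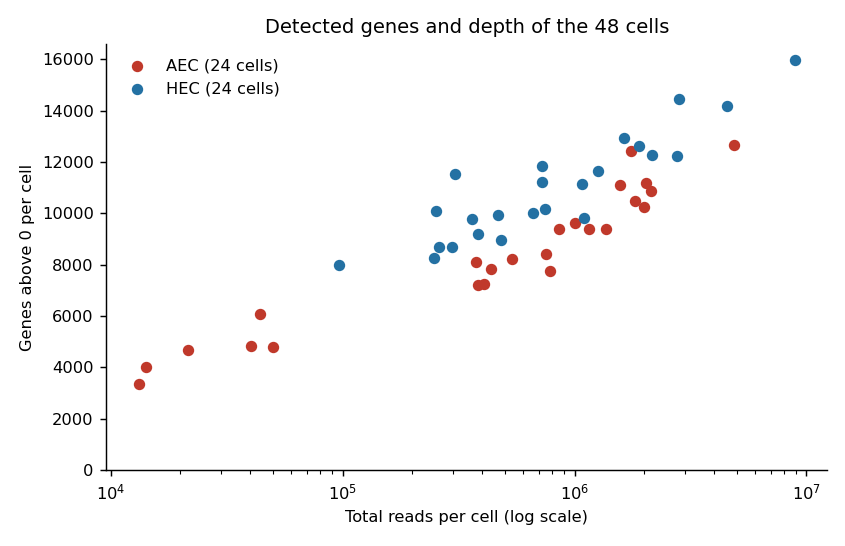
Genes above 0 per cell against the total reads per cell (log scale), with 1 point for each of the 24 AEC cells (red) and the 24 HEC cells (blue). The 6 shallowest AEC cells hold 13261 to 50126 reads, and the median is 8317 genes in AEC cells and 10645 genes in HEC cells.

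The series concerns alternative splicing while hematopoietic stem cells emerge, and the comparison of HEC with AEC cells asks how gene levels and isoform use differ between these populations. *Runx1*, the transcription factor that endothelial cells need to turn into blood cells, was higher in HEC cells, with a mean of 2.49 reads per 10000 (SD 1.37 between cells) against 0.438 (SD 0.651) in AEC cells. *Neurl3*, a ubiquitin ligase gene known from hemogenic endothelium, had means of 2.51 (SD 1.25) and 0.376 (SD 0.456). *Kit*, the receptor for stem cell factor, had means of 1.83 (SD 1.19) and 0.296 (SD 0.524), and *Myb*, a transcription factor of definitive blood formation, had means of 1.43 (SD 0.836) and 0.169 (SD 0.558). *Gfi1*, a repressor that acts downstream of *Runx1*, averaged 0.709 (SD 0.764) in HEC cells and 0.105 (SD 0.264) in AEC cells. The arterial gap junction gene *Gja5* ran the other way, with a mean of 12.4 (SD 11.2) in AEC cells and 4.09 (SD 8.27) in HEC cells.

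Among 3294 genes that passed a minimum of level and detection, the 12 with the highest log2 ratio of HEC over AEC cells were *Hspa1a* (3.14), *Alox5ap* (2.90), *Itgb3* (2.62), *Myb* (2.51), *Ptpn6* (2.46), *Neurl3* (2.45), *Hspa1b* (2.40), *Kit* (2.28), *Runx1* (2.27), *Adgrg1* (2.24), *Cd47* (2.08) and *Pla2g4a* (1.96). The difference of the means was larger than the SD between cells in either group for each of these genes except *Pla2g4a*. *Hspa1a*, which encodes an inducible heat-shock protein, rose from a mean of 0.776 (SD 0.856) to 7.65 (SD 4.99). *Alox5ap* and *Pla2g4a* act in the release of arachidonic acid and its use for leukotrienes. *Adgrg1*, an adhesion receptor of blood stem cells, had means of 0.891 (SD 1.32) in AEC cells and 4.57 (SD 2.04) in HEC cells. *Ptpn6*, a phosphatase of blood cells, had means of 0.112 (SD 0.193) and 1.06 (SD 0.645).

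*Runx1* (ENSMUSG00000022952, mm10 chromosome 16, 92601466 to 92826149) reached a value of 1 or more in 21 of 24 HEC cells, or 87.5% (exact Clopper-Pearson 95% interval 67.6 to 97.3%). In AEC cells it did so in 4 of 24, or 16.7% (interval 4.74 to 37.4%). Its 11032 reads in HEC cells and 690 reads in AEC cells corresponded to pooled levels of 3.23 per 10000 (exact Poisson 95% interval 3.17 to 3.29) and 0.283 (interval 0.262 to 0.304). PCR copies are not independent molecules, so such intervals cover counting error only. Pooling also weighs cells by depth. HEC 1, the deepest cell with 8897958 reads, had *Runx1* at 5.48, whereas the mean over HEC cells was 2.49. *Neurl3* reached 1 in 20 HEC and 2 AEC cells, *Kit* in 20 and 3, *Myb* in 15 and 1, and *Gfi1* in 5 and 1. AEC 6 alone held 67.0% of the AEC sum of *Myb*, whose log2 ratio without that cell was 3.27. *Gfi1b*, the paralog of *Gfi1*, had a log2 ratio of 0.31, and the same cell held 94.5% of its AEC sum; the ratio was 1.45 without it, -0.07 without HEC 11, and -0.65 without the 6 cells of each group with the fewest genes. *Ptprc*, which encodes the pan-leukocyte antigen CD45, stayed under 1 in every cell, with 553 reads over the HEC cells and 6 over the AEC cells.

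The list of hemogenic and early hematopoietic genes had a median log2 ratio of 0.99 over 26 members used, of which 22 were higher in HEC cells, at percentile 100 of random lists of like level. Without the 6 cells of each group with the fewest genes the median was 2.06, and without AEC 7 alone it was 1.74. *Hlf*, a transcription factor gene of blood stem cells, had a log2 ratio of 2.38, *Spn* one of 2.10, *Ikzf2* 1.91, *Spi1* 1.83 and *Ikzf1* 1.41. *Cd44*, an adhesion receptor gene, was higher by 0.96 on the log2 scale, with means of 2.10 (SD 1.02) in HEC and 1.03 (SD 1.12) in AEC cells. *Procr*, which encodes the endothelial protein C receptor, had a log2 ratio of -0.34, less than the spread between cells. The surface markers or reporters of the sort are not given in the sources used here, and a gene used to choose cells would differ between the groups by that choice.

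**Figure D2:**
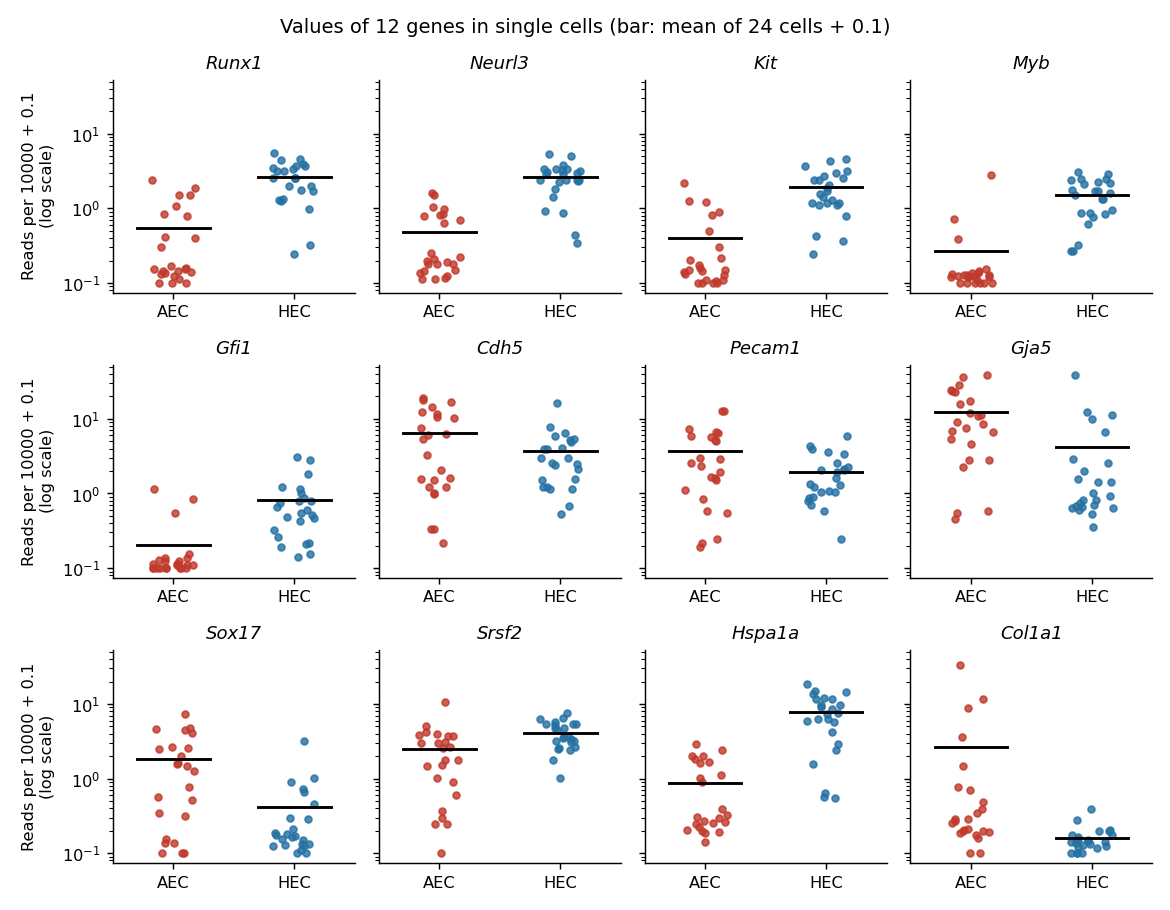
Reads per 10000 plus 0.1 (log scale) of 12 genes in each AEC cell (red) and each HEC cell (blue), with the mean of the 24 cells as a black bar. *Runx1* reaches 1 or more in 21 HEC cells and 4 AEC cells, and *Gja5* averages 12.4 in AEC and 4.09 in HEC cells.

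The arterial program was lower in HEC cells. The arterial list had a median log2 ratio of -1.61 over 19 members used, of which 18 were lower, at percentile 0 of random lists. Its members summed to 51.0 (SD 30.8) in AEC cells and 16.1 (SD 15.2) in HEC cells. *Sox17*, a transcription factor gene of arterial endothelium, had a log2 ratio of -2.16 and reached 1 in 13 AEC cells and 1 HEC cell. The Notch effector genes *Hey2* and *Hey1* had log2 ratios of -1.98 and -1.36, the Notch ligand gene *Dll4* -1.56, and the receptor gene *Notch1* -1.94, which was -1.26 without the 6 cells of each group with the fewest genes. *Gja4*, another connexin gene, fell from a mean of 9.97 (SD 9.98) to 2.26 (SD 3.65), a log2 ratio of -2.09. *Cxcl12*, a chemokine gene, had the lowest ratio of the list at -3.06, which was -0.95 without the 6 cells of each group with the fewest genes and the 4 cells with little *Cdh5* and *Kdr* (AEC 11, 19 and 20 and HEC 20). *Efnb2* (-1.05) and *Bmx* (-0.96) were also lower. *Gja5* (ENSMUSG00000057123, chromosome 3, 96904693 to 97077416) had a log2 ratio of -1.58, and HEC 12 alone reached 39.1; the ratio was -2.23 without that cell. For each of the 19 members the difference of the means lay within the SD between AEC cells.

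Pan-endothelial genes were lower as well, with a median of -0.97 over 18 members, of which 16 were lower. *Cdh5*, which encodes VE-cadherin, had means of 6.32 (SD 6.24) in AEC and 3.60 (SD 3.38) in HEC cells, a log2 ratio of -0.80, and *Pecam1* had a ratio of -0.92. *Ecscr* (-1.74), *Robo4* (-1.54), *Cldn5* (-1.46) and the VEGF receptor gene *Kdr* (-1.45) were the members with the largest differences, whereas *Erg*, an endothelial transcription factor gene, was higher by 1.25. The list of venous genes had a median of -1.54 over 6 members used, all lower, with *Dab2* at -2.56, *Flt4* at -1.94, *Nrp2* at -1.73 and *Nr2f2* at -1.36. AEC 7 held 79.0% of the AEC sum of *Nrp2*, whose ratio was -0.43 without that cell, and *Nr2f2* was at -0.81 without AEC 11. Notch targets and modulators, of which 8 members used were also on the arterial list, had a median of -1.46, with *Notch4* at -1.98 and *Jag1* at -1.95 but *Hes1* at 0.93; the median was -0.83 without the 4 cells with little *Cdh5* and *Kdr*. Genes of extracellular matrix and adhesion were lower in HEC cells for each of 17 members used, with a median of -1.18. Within that list the basement membrane genes *Nid1* (-2.21) and *Col4a2* (-2.02) differed beyond the SD of either group, and *Fbn1* (-1.80) and *Lamc1* (-1.66) followed.

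Splicing factors were compared because of the subject of the series. Scaling each cell by a median-of-ratios factor instead of its total moved the median of all genes from 0.04 to -0.50, so the lists that follow are also given relative to that shift of the median, although single genes shifted by more or less than that. SR splicing factors, which mark exons for splicing, were higher in HEC cells for each of 14 members, with a median log2 ratio of 0.39 at percentile 97.9, but the median was -0.16 with median-of-ratios scaling and 0.34 relative to its shift. *Srsf2* (ENSMUSG00000034120, chromosome 11, 116849901 to 116853094) had means of 3.98 (SD 1.62) in HEC and 2.40 (SD 2.30) in AEC cells, a log2 ratio of 0.71, and 0.20 with that scaling. *Srsf5* (1.02), *Srsf6* (1.00), *Srsf10* (0.92) and *Srrm1* (0.78) had larger ratios, and *Srsf1* (0.49) and *Srsf3* (0.19) smaller ones that turned to -0.04 and -0.71 with that scaling. The core spliceosome list had a median of 0.33 over 35 members, of which 29 were higher, but of -0.31 with median-of-ratios scaling and 0.19 relative to its shift; *Sf3b2* (0.84), *Eftud2* (0.74), *Prpf31* (0.73) and *Ddx5* (0.70) led it. The hnRNP list had a median of 0.30 over 21 members, but of -0.28 with that scaling and 0.22 relative to its shift. *Ptbp1*, a splicing repressor gene, was at 0.85, *Hnrnpa1* at 0.71 and *Hnrnpu* at 0.70, and *Hnrnpf* was at -0.86, of which AEC 12 held 63.5% of the AEC sum and without which it was 0.51. Tissue splicing regulators had a median of 0.42 over 16 members used, but of -0.22 with that scaling and 0.28 relative to its shift, with *Rbm38* at 1.39, *Celf2* at 1.25, *Khdrbs1* at 0.81 and *Nova2* at -1.92, which was -0.79 without AEC 10. The summed level of the SR list was 27.4 (SD 10.2) in AEC and 37.7 (SD 6.93) in HEC cells, and that of the core spliceosome was 67.2 (SD 18.5) and 83.8 (SD 13.02), a difference within the SD between AEC cells.

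Genes of ribosome production were higher in HEC cells. Ribosome biogenesis genes were higher for each of 18 members, with a median log2 ratio of 1.00 at percentile 100, of 0.55 with median-of-ratios scaling and of 1.05 relative to its shift. Their sum rose from 33.0 (SD 18.7) to 69.3 (SD 16.3), beyond the spread between cells. *Rrs1* was at 1.57, the gene of the nucleolar methyltransferase fibrillarin, *Fbl*, at 1.49, the nucleolin gene *Ncl* at 1.34 and *Wdr43* at 1.29. Cytosolic ribosomal protein genes had a median of 0.39, with 41 of 42 members higher, but of -0.54 with median-of-ratios scaling and -0.04 relative to its shift; *Rps3* (0.90), *Rpl3* (0.88), *Rps2* (0.88) and *Rpl4* (0.82) had the largest ratios. Mitochondrially encoded genes had a median of 0.34 over 13 members, but of -0.59 with that scaling and -0.09 relative to its shift, with *mt-Nd1* at 0.60, *mt-Nd6* at 0.58, *mt-Nd5* at 0.49 and *mt-Co3* at -0.57.

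Glycolysis genes had a median of 0.38 over 15 members used, but of -0.34 with median-of-ratios scaling and 0.16 relative to its shift. *Hk2* (1.19), *Pfkm* (0.92) and the pyruvate kinase gene *Pkm* (0.89) were higher, and the lactate transporter gene *Slc16a3* was at -1.25. Nuclear genes of oxidative phosphorylation had a median of -0.27 over 20 members, of -1.15 with that scaling and of -0.65 relative to its shift, with *Ndufb8* at -0.92, *Cox4i1* at -0.73, *Cycs* at -0.72 and *Atp5a1* at 0.63. S phase genes had a median of 0.19 and G2/M phase genes of 0.17, at percentiles 83.7 and 80.1, but of -0.49 and -0.35 with that scaling and 0.01 and 0.15 relative to its shift. In these lists *Tipin* (0.96), *Cdc20* (1.42), *Aurka* (1.01) and *Bub1b* (0.92) were higher, and *Hells* (-1.42), *Rrm2* (-1.08), *Rfc2* (-0.99) and *Plk1* (-1.03) lower. AEC 1 held 60.2% of the AEC sum of *Hells*, whose ratio was -0.23 without that cell.

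Genes of inflammatory and interferon signaling were lower in HEC cells, with a median of -0.47 over 14 members used at percentile 1.07. *Nfkbia*, an inhibitor gene of NF-kB, was at -1.88, *Ifitm3* at -1.16 and *Bst2* at -0.93, the last with 42.6% of its AEC sum in AEC 21 and a ratio of -0.24 without that cell. Genes that tissue dissociation is known to induce were higher in HEC cells, with a median of 1.20 over 16 members, of which 15 were higher, at percentile 100. Besides *Hspa1a* and *Hspa1b*, the immediate-early genes *Fosb* (1.79), *Ier3* (1.74), *Jun* (1.45) and *Fos* (1.19) were among them. Their sum was 33.1 (SD 9.52) in AEC cells and 72.5 (SD 19.1) in HEC cells.

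**Figure D3:**
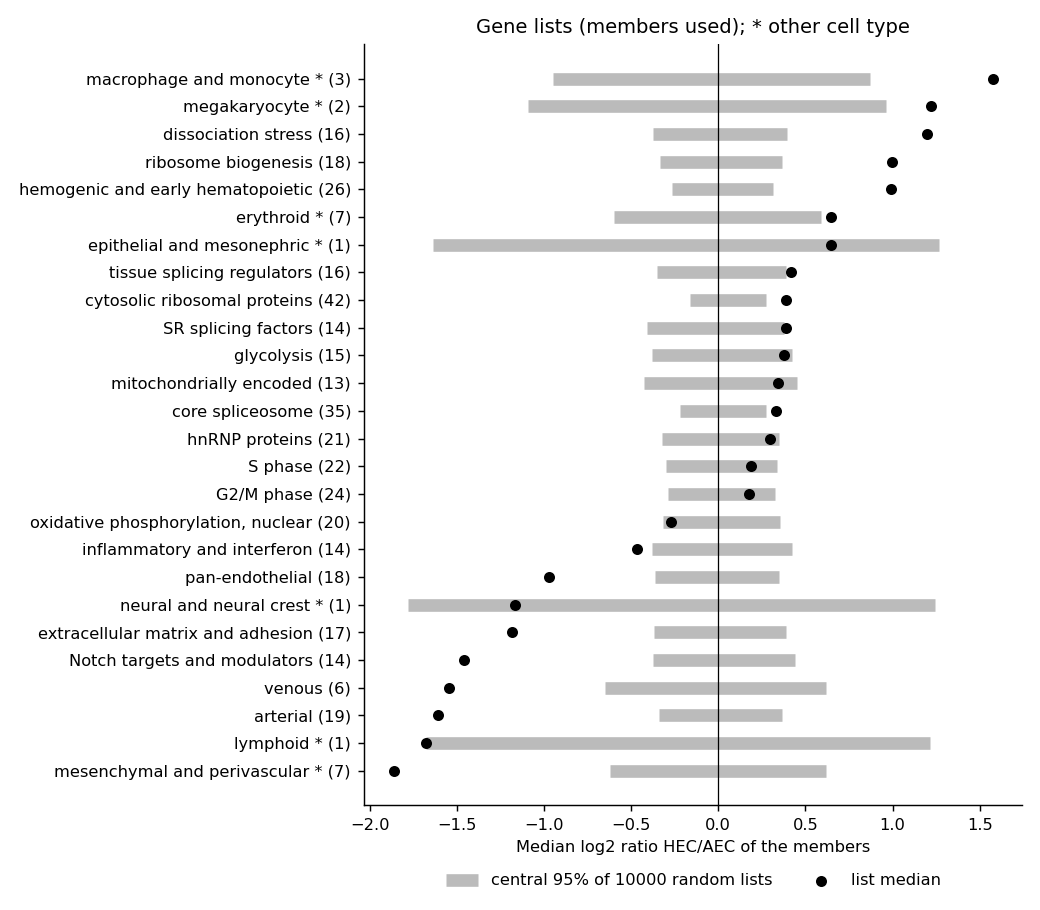
Median log2 ratio of HEC over AEC cells for each gene list except the sex-linked genes (points; number of members used in brackets) with the central 95% of 10000 random lists of like level (grey). Arterial genes are at -1.61 and ribosome biogenesis genes at 1.00; with median-of-ratios scaling 10 of the 27 list medians changed sign, and relative to its shift 2 did, those of ribosomal proteins and mitochondrially encoded genes.

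Marker genes of other cell types were compared as well. The embryonic globin genes *Hba-x* and *Hbb-y* reached 1 in all cells, and *Hba-x* had means of 6.71 (SD 7.88) in AEC and 10.6 (SD 7.49) in HEC cells. The erythroid list had a median log2 ratio of 0.65 over 7 members used, all of them globin genes, and of 1.84 without the 6 cells of each group with the fewest genes; *Hbb-bt* was at 0.96 and *Hbb-bh1* at 0.86. *Klf1*, an erythroid transcription factor gene, was at -1.05, with 89.9% of its AEC sum in AEC 6 and a ratio of -0.03 without that cell. Macrophage and monocyte genes had a median of 1.57 over 3 members used, *Mpo* (1.71), *Lyz2* (1.57) and *Cd68* (1.34), with *Csf1r* at 0.76. Over all members found the median was 0.70, and it was 0.32 with a pseudocount of 1. Megakaryocyte genes had a median of 1.22 over 2 members used, of which *Itgb3* was higher and *Plek* (-0.18) lower. Their median over all members found was 0.32. *Pf4* was at 0.46 and *Gp9* at 0.18, the latter with a lowest value of -0.09 when single cells were left out.

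Mesenchymal and perivascular genes were lower in HEC cells, with a median of -1.86 over 7 members used, among them *Col1a1* (-4.08), *Col3a1* (-2.47), *Col1a2* (-1.97) and *Postn* (-1.86). *Acta2*, a smooth muscle actin gene, was abundant, with means of 12.8 (SD 29.0) in AEC and 5.08 (SD 6.01) in HEC cells, a log2 ratio of -1.32 that was 1.70 without both sets of cells named in this paragraph. Without AEC 19 *Col3a1* was at -1.54, and without AEC 11 *Postn* was at -1.03. Without the 4 cells with little *Cdh5* and *Kdr* the median was -0.28, and without these and the 6 cells of each group with the fewest genes it was 0.31. The lists of lymphoid, neural and epithelial genes each rested on 1 member used: *Ebf1* was at -1.68, *Stmn2* at -1.17 and *Krt18* at 0.64, the last at 1.04 without AEC 18. The median over all members found was 0.01 for the lymphoid list, with *Cd79b* at -0.44, and 0.04 for the neural list, with *Elavl4* at 0.07. The epithelial list, with *Krt8* at 0.45, was at -0.04 with median-of-ratios scaling. The sex-linked genes had a median of 0.32, with *Eif2s3y* at 0.43, *Ddx3y* at 0.36, *Xist* at 0.32 and *Kdm5d* at 0.21 (lowest -0.10 when single cells were left out), none beyond the spread between cells.

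The 12 genes with the lowest log2 ratio were *Rreb1* (-4.67), *Col1a1* (-4.08), *Bcr* (-3.75), *Mdn1* (-3.60), *Peg3* (-3.57), *Ddx18* (-3.49), *Nqo2* (-3.35), *Kitl* (-3.35), *Actc1* (-3.33), *Atp11a* (-3.29), *Srgap3* (-3.17) and *Gm6211* (-3.09). For 11 of them a single AEC cell held more than 50% of the AEC sum, all but *Actc1*. *Rreb1* owed 99.2% of its AEC sum to AEC 10, *Mdn1* 95.8% and *Ddx18* 94.5% to AEC 7, and *Srgap3* 99.2% to AEC 1; without that cell their ratios were 1.33, 0.44, 0.51 and 0.77. *Bcr* and *Nqo2* rested on AEC 7 and were at -0.84 and -1.15 without it. *Kitl* rested on AEC 12 (-0.66 without it), *Peg3* (-1.99) and *Gm6211* (-0.92) on AEC 10, *Atp11a* (-0.99) on AEC 1 and *Col1a1* (-3.09) on AEC 19. *Col1a1* and the cardiac actin gene *Actc1* were at -1.71 and -1.68 without the 4 cells with little *Cdh5* and *Kdr*. Without the 6 cells of each group with the fewest genes the 12 lowest genes shared 2 with this list, *Col1a1* and *Actc1*, and the 12 highest shared 9 with theirs. *Tm4sf1*, *Igfbp3*, *Cavin2* and *Gja4* then stood among the lowest.

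Isoform shares, the percent of a gene's summed value held by each annotated transcript, were compared next. The reads of *Gfi1* were assigned to different transcripts in the groups: Gfi1-203 (ENSMUST00000159164) held 78.0% in HEC and 2.16% in AEC cells, and Gfi1-202 (ENSMUST00000065478) held 8.70% and 97.8%. Both transcripts have 7 exons and lie on the minus strand of chromosome 5. They share the 5' end at 107725805 and have their 3' ends at 107716657 and 107716666. Their lengths, 2648 and 2639 bases, differ by as much as their 3' ends, so these values show no difference in splicing between them. The positions of their inner exons were not compared. The AEC cells held 76 reads of *Gfi1* against 3804 in HEC cells, but the shares are of summed values, in which reads of shallow cells weigh more. The highest AEC values of *Gfi1* were those of AEC 18 (1.04), AEC 7 (0.754, the value of 1 read) and AEC 8 (0.453, where 1 read stood for 0.227). Over the cells with *Gfi1* reads, the mean share of Gfi1-202 was 80.0% (SD 41.4, 15 AEC cells) and 20.8% (SD 41.5, 24 HEC cells). For these means, SDs of this size arise only if Gfi1-202 took all or none of a cell's *Gfi1* reads. How reads were divided between 2 transcripts this alike was not tested, so the shares do not show a change of isoform use by the cells. Gfi1-201 held 13.3% in HEC cells.

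For *Runx1*, the 8-exon transcript Runx1-201 (ENSMUST00000023673) held 60.8% in AEC and 76.1% in HEC cells, and the 5-exon transcript Runx1-202 held 6.29% and 16.8%. The retained-intron transcript Runx1-206 held 12.03% and 1.38%, and the processed transcript Runx1-207 held 15.1% and 1.00%. AEC 17 weighed most on 2 of these, since without it the differences were 3.17 points for Runx1-201 and -1.64 for Runx1-207. The difference for Runx1-206 was -3.09 points without AEC 16. Without the 6 cells of each group with the fewest genes, the difference grew from 15.3 to 43.4 points for Runx1-201. It went from -10.6 to -22.5 for Runx1-206 and from -14.1 to -24.8 for Runx1-207, but from 10.5 to 7.87 for Runx1-202. The difference for Runx1-201 turned to -8.69 points when transcripts under 5% of their gene were removed, and that for Runx1-202 to -5.49 points by the mean of the shares of single cells. For *Kit*, the annotated retained-intron transcript Kit-208 held 41.3% in AEC and 69.2% in HEC cells. Its difference was 10.5 points without AEC 1 and -6.41 without the 6 cells of each group with the fewest genes. Kit-208 has 5 exons and 3175 bases at the 3' end of the gene, against 21 exons of Kit-201 and Kit-204. Whether the reads assigned to it cover a retained intron was not tested. Kit-204 held 32.0% and 10.6%, with a difference that turned to 7.28 points without AEC 1, and Kit-201 held 26.7% and 19.99%, with a difference of 7.13 points without AEC 8. *Srsf2* kept similar shares: Srsf2-201 held 74.7% and 80.6%, and Srsf2-204, a transcript subject to nonsense-mediated decay, held 11.8% and 11.3%. *Cd44* was spread over Cd44-207 (77.0% in AEC and 70.2% in HEC cells), Cd44-203 (16.02% and 17.05%) and the 19-exon transcript Cd44-201 (1.81% and 10.9%; a difference of 5.64 points without HEC 15). The small differences of Srsf2-204, Cd44-203 and Kit-201 changed direction by the mean of the shares of single cells. *Ptprc* had too few AEC cells with reads for shares.

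**Figure D4:**
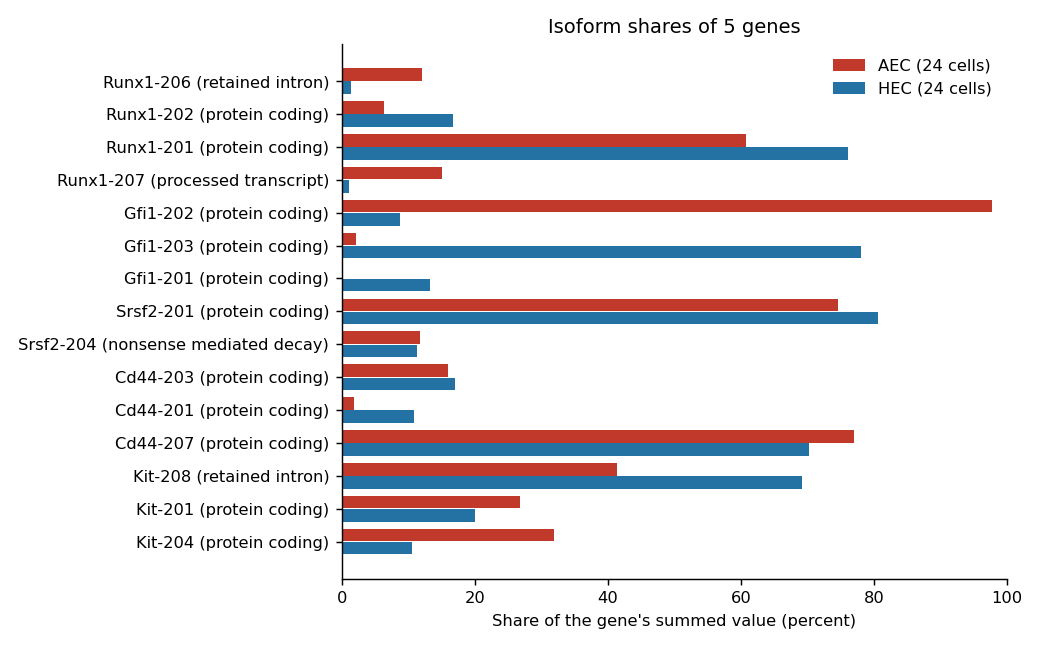
Share of the gene's summed value over the 24 AEC cells (red) and the 24 HEC cells (blue) held by the isoforms of *Runx1*, *Gfi1*, *Srsf2*, *Cd44* and *Kit*, in percent. Gfi1-203 holds 2.16% in AEC and 78.0% in HEC cells, and Srsf2-201 holds 74.7% and 80.6%. In each cell with *Gfi1* reads, Gfi1-202 took all or none of them.

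Across 1032 genes with enough reads in both groups and 4975 isoforms, the largest difference of an isoform's share had a median of 3.86 points per gene. Among the 8 genes with the largest differences were *Gimap6*, *Chd7*, *Eif1a*, *Cdc16*, *Anapc5*, *Ndufv2* and *Pkn2*. Chd7-202, a 38-exon transcript of a chromatin remodeler gene, rose from 20.2% in AEC to 64.9% in HEC cells, and Anapc5-201 and Cdc16-205 belong to subunits of the anaphase-promoting complex. Anapc5-201 rose from 34.7% to 76.5%, with a difference of 25.97 points without AEC 12, and the retained-intron transcript Cdc16-205 went from 55.0% to 12.6%. Pkn2-201 rose from 27.7% to 68.6%. Eif1a-202 went from 46.7% to 4.24%, with a difference of -25.6 points without AEC 23. Ndufv2-201 went from 64.2% to 22.9%, with a difference of -11.1 points without AEC 10. Gimap6-203 went from 57.3% to 6.69%, a difference that turned to 2.26 points without AEC 1. By the mean of the shares of single cells all 8 differences kept their sign but were smaller, such as -1.02 points for Gimap6-203, -10.05 for Ndufv2-201, 15.2 for Pkn2-201 and -17.01 for Eif1a-202, and without the 6 cells of each group with the fewest genes 7 of 8 kept their sign.

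Transcript types differed little. Over genes with such a transcript, retained-intron transcripts held 3.54% (SD 1.36) in AEC and 3.13% (SD 0.720) in HEC cells. Transcripts subject to nonsense-mediated decay held 10.4% (SD 6.62) and 8.42% (SD 2.15), and 7.99% and 8.24% without the 6 cells of each group with the fewest genes, a change of direction.

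More isoforms were detected per gene in HEC cells, with a median of 1.33 per detected gene (range 1.19 to 1.71) against 1.23 (range 1.06 to 1.47) in AEC cells. The percent of detected genes with 2 or more isoforms was 24.4% and 17.8%. After thinning to 200000 reads the medians were 1.27 and 1.21 isoforms per gene and 20.8% and 16.8% of genes. After thinning to 10000 reads they were 1.109 and 1.096 isoforms per gene, within the spread between cells. Over the 855 genes above 0 in all cells, which include *Rps3* and *Hnrnpa1*, the medians were 1.90 in HEC and 1.59 in AEC cells, a difference close to the SD of 0.331 between HEC cells. For those of these genes detected after thinning to 200000 reads, the medians were 1.738 (SD 0.105) and 1.496 (SD 0.102), beyond the spread between cells. For those detected after thinning all cells to 10000 reads, the medians were 1.265 (SD 0.020) in HEC and 1.206 (SD 0.050) in AEC cells. The percent of them with 2 or more isoforms was then 20.8% (SD 1.51) and 16.9% (SD 3.62). Both differences lay beyond the SD of either group, unlike that over all detected genes at this depth. With transcripts at 0.5 or more, the percent turned to 8.64% in HEC and 9.02% in AEC cells, within the spread between cells.

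Each cell was also compared with its nearest neighbours. Of the HEC cells, 23 of 24 had at least 3 of their 5 nearest neighbours in their own group, and of the AEC cells 12 of 24. HEC 7, with *Gja5* at 12.3 and *Runx1* at 0.145, had no HEC cell among its 5 neighbours but 2 when 3000 genes were used. AEC 6, with *Runx1* at 1.41 and *Myb* at 2.71, had no AEC cell among its neighbours, nor did AEC 8, 12 and 17, of which AEC 8 and 12 were among the shallowest; with 3000 genes the AEC cells without an AEC neighbour rose from 4 to 8.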

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

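A small part of the reads lay on 128 transcript identifiers without a match in the annotation, which no comparison of genes used. These reads made up a median of 0.0931% of a cell's reads in AEC cells, with 28304 reads in all, and 0.0784% in HEC cells, with 27252 reads. They stand here because they are a signal outside the main measurement and lie above the 3 reads that a count of 0 allows in each group. All cells of both groups held such reads, at most 0.174% of a cell. No test of their source was run, and no biological explanation was tested.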

How the results depend on the processing

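Of the alternatives, those without the 4 cells with *Cdh5* and *Kdr* under 0.5, without both sets of cells, and relative to the shift of all genes were chosen after seeing the data, as were the lists of chaperones and others. For single genes and isoforms, the sizes from which a change of sign is given (1 on the log2 scale, 20 points) were also set after the values had been seen. No paired analysis was possible because the numbers 1 to 24 name cells, and no test was run.

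Of 27 list medians, 14 kept their sign under each of the 14 alternatives, among them the arterial, pan-endothelial, venous, hemogenic, ribosome biogenesis, extracellular matrix, Notch and dissociation stress lists; 22 did so without the raw median-of-ratios values, and 24 without any median-of-ratios value. With that scaling 10 lists turned below 0: SR proteins (-0.16), core spliceosome (-0.31), hnRNP proteins (-0.28), tissue splicing regulators (-0.22), S phase (-0.49), G2/M phase (-0.35), ribosomal proteins (-0.54), mitochondrially encoded genes (-0.59), glycolysis (-0.34) and epithelial genes (-0.037). The chaperone list turned to -0.051. The extracellular matrix list moved to -2.02 and oxidative phosphorylation to -1.15. The factor is the same for all genes of a cell, but the ratios of single genes shifted by different amounts. Relative to the shift of the median of all genes, only ribosomal proteins (-0.038) and mitochondrially encoded genes (-0.085) stayed below 0 among those 10, with oxidative phosphorylation at -0.65.

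Without the 6 cells of each group with the fewest genes, the hemogenic list moved to 2.06 and the erythroid list to 1.84; without both sets of cells they were at 1.98 and 1.81. The mesenchymal list moved to -0.28 without the 4 cells with little *Cdh5* and *Kdr* and turned to 0.31 without both sets, as *Col3a1* (0.31) and *Postn* (0.70) did. Among the genes named by rule, the ratios of *Rreb1*, *Mdn1*, *Ddx18*, *Srgap3* and *Nrp2* also turned, to 1.34, 0.55, 0.42, 0.77 and 0.27 without the 6 cells, and to 1.57, 0.69, 0.61, 0.78 and 0.23 without both sets. Leaving out each cell in turn, the first 4 ranged from -4.81 to 1.33, -3.94 to 0.44, -3.62 to 0.51 and -3.28 to 0.77. All 5 ratios rested on a single shallow AEC cell each. Some other list members turned as well, such as *Acta2* to 1.70 and *Dlk1* to 0.96 without both sets.

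With all members found, and so more genes near 0, the lymphoid list turned to 0.0056 and the neural list to 0.039, and the macrophage (0.70) and megakaryocyte (0.32) lists moved. The pseudocount weighs on low genes: with 0.01 the lymphoid list was at -2.91 and the macrophage list at 2.75, and with 1 they were at -0.37 and 0.32 and the venous list at -0.47. By the difference of mean log2(value + 1), the lymphoid (-0.25), macrophage (0.26), mesenchymal (-0.28), venous (-0.37) and Notch (-0.32) lists were closer to 0. In all, 337 of 372 list medians, 1324 of 1463 log2 ratios of single genes and 127 of 136 isoform differences counted as unchanged under alternatives. These moved by less than the spread between cells, and the lists kept their sign. Single genes and isoforms kept theirs only where they reached the sizes given above, since smaller ones were not checked for it. The spread is wide: Ndufv2-201 counted as unchanged although it went from -41.3 to -11.1 points without AEC 10. The differences of the median detected genes and transcripts also moved by less than the spread between cells, although some shrank strongly. They fell from 2328 to 200.5 genes and from 4215.5 to 86.5 transcripts at values of 0.5 or more. After thinning to 10000 reads they were 313 genes and 394 transcripts, and after thinning to 200000 reads 2125 and 3164.5. The filter of a mean of at least 1 left members, and so gave a value, for 21 of the 27 lists, and the 5% filter kept 21 of 23 isoforms.

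The difference of the median isoforms per gene was 0.304 over the genes above 0 in all cells, larger than over all genes. The difference of the percent of genes with 2 or more isoforms turned to -0.379 points for transcripts at 0.5 or more; the cause was not tested. Of the isoforms, Gimap6-203 turned to 2.12 points and Kit-204 to 7.47 without the 6 cells, and Kit-208 to -6.41. When each cell was left out in turn, Gimap6-203 ranged from -51.9 to 2.26 and Kit-204 from -27.5 to 7.28, both highest without AEC 1. The counts of AEC and HEC cells with neighbours of their own label were 10 and 23 with 3000 genes and 12 and 23 without the cell cycle and ribosomal lists.

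Depth limits the AEC values most, since in a cell of 13261 reads a single read is worth 0.754 per 10000, so low genes and the isoform shares of *Gfi1* and *Kit* in AEC cells rest on few reads.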

Other observations

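The gene lists in the first paragraph and the tests of the 3 patterns of globins, detection and stress genes were chosen only after the results had been seen.

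Imprinted genes were lower in HEC cells, with a median log2 ratio of -1.17 over 19 members used, of which 17 were lower, at percentile 0 of random lists; without both sets of cells named above the median was -0.67. *Meg3*, a maternally expressed noncoding RNA, was at -3.04, *Mest* at -1.61 and the growth factor gene *Igf2* at -1.06, whereas *Kcnq1ot1* was at 0.97. Genes of serine, one-carbon and purine synthesis had a median of 0.64 over 18 members (0.25 with median-of-ratios scaling), with *Phgdh*, the first enzyme gene of serine synthesis, at 1.67 and means of 0.661 (SD 1.08) in AEC and 2.32 (SD 1.39) in HEC cells. *Shmt2* was at 1.64, *Atic* at 1.38 and *Impdh2* at 1.36. Caveolae genes had a median of -1.49 over 7 members, with *Cavin2* at -2.74 and *Cav1* at -2.28. The host genes of small nucleolar RNAs had a median of 0.70 over 10 members used (0.18 with median-of-ratios scaling), with *Snhg15* at 1.71 and *Gas5* at 0.63, the latter at -0.34 with that scaling.

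Some cells held values unlike those of their group. AEC 11, 19 and 20 had *Cdh5* at 0.238, 0.119 and 0.234, *Col1a1* at 11.7, 33.3 and 8.69 and *Actc1* at 54.5, 31.4 and 135. HEC 20 had *Cdh5* at 0.424, *Kdr* at 0.120 and *Col3a1* at 4.99. AEC 6, with *Runx1* at 1.41 and *Myb* at 2.71, and HEC 7, with *Gja5* at 12.3 and *Runx1* at 0.145, each had 5 neighbours of the other label, although HEC 7 had 2 HEC neighbours with 3000 genes. Among cells with at least 200000 reads, *Hba-x* ranged from 2.06 to 4.43 in AEC cells, with AEC 6 the highest, and from 5.35 to 41.4 in HEC cells, with HEC 7 at 5.88. In AEC 8, 34.9% of the reads lay on CT010467.1, a gene model that holds ribosomal RNA. *Xist* and the Y-linked gene *Ddx3y* each varied between cells of both groups, with *Ddx3y* at 1 or more in 4 AEC and 4 HEC cells and *Xist* in 3 and 6.

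Reads of *Hba-x* were present in all cells, at 1 or more in 48 of 48. In cells with at least 200000 reads, the log2 ratio of *Hbb-y* to *Hba-x* had an SD of 0.318 between AEC and 0.122 between HEC cells, at percentile 0 among random gene pairs of like level in both groups, while the median of *Hbb-y* was 5.08 in AEC and 14.8 in HEC cells. RNA or reads from other cells in amounts that vary by cell remain a candidate explanation, but the ratio test cannot decide it. Globin genes expressed together in the cells themselves would also keep a steady ratio. Whether whole red cells or RNA in the fluid carried such reads was not tested. A constant share in every cell is argued against by HEC cells, in which the SD of *Hbb-y* lay at percentile 92.4 of genes of like level, although in AEC cells it lay at 0.510, and the ratio test was chosen after this outcome. In the cells with at least 200000 reads, *Hba-x* ranged from 2.06 to 4.43 in AEC and from 5.35 to 41.4 in HEC cells, without overlap. This held for AEC 6 (4.43) and HEC 7 (5.88), whose nearest neighbours were mostly of the other label. Among cells with fewer reads, AEC 1, 7, 8, 10, 12 and 21 held *Hba-x* at 9.20 to 28.3 and HEC 8 at 14.8. Whether RNA or reads from other cells differed by group or by depth was not tested. Transcription of globin genes in the cells themselves was not tested either and stays open.

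More genes and isoforms were detected per HEC cell. Thinning to 200000 reads left a difference of 2125 genes between the medians, against an SD of 869 between cells, which argues against sequencing depth as the whole cause in the cells with that many reads, whereas with all cells thinned to 10000 reads the difference was 313 genes, within the SD of 464 between AEC cells. Of 15 neural, epithelial and lymphoid marker genes, HEC cells held a mean of 3.35 (SD 1.23) and AEC cells 2.22 (SD 1.26) at 200000 reads. The ratio was 1.51 against 1.30 for all genes, so more shared low-level reads in HEC cells stay open. That ratio met the first bar set for it, but the excess lay within the SD between cells. The bar of the SD was added after the ratio was known. Reads of *Hba-x* and *Hbb-y* together at 200000 reads ranged from 107 to 380 in AEC and from 291 to 2268 in HEC cells. HEC 9, with the most, also had the most genes (10706). AEC 17, highest of the AEC cells, had 6610 genes against an AEC mean of 6581. The source of the globin reads is itself open, so they do not decide this. Fewer molecules captured per AEC cell cannot be told apart from the group, since no molecule count or spike-in value was used here, and the difference at values of 0.5 or more was 200.5 genes. A difference between the populations in the number of genes they express was not tested and stays open.

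Heat-shock and immediate-early genes were higher in HEC cells, with *Hspa1a* at 3.14 and *Fosb* at 1.79. AEC cells with few detected genes are argued against as the source, since the median of the list was 1.47 without the 6 cells of each group with the fewest genes. The wider chaperone list had a median of 0.62 over 22 members, of which 20 were higher, with *Fkbp4* at 1.57 and *Hsp90aa1* at 1.41, but of -0.05 with median-of-ratios scaling and 0.45 relative to its shift. A difference in handling between the sorted groups cannot be told apart from the difference between the populations, because each group holds only its own cells and the sort times are not given in the sources used here. A biological difference between the populations stays open and was not tested.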
